A study of Mus musculus with 8 samples.

How the data were processed

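Total RNA of round spermatids of 4 Miwi (Piwil1) genotypes was measured on 8 Affymetrix arrays, 2 per genotype. Per the labels' protocols, testes of adult C57BL/6 mice were digested with collagenase, spermatids were separated on a gradient of 2 to 4% bovine serum albumin, and RNA extracted with Trizol was labelled with biotin. The titles call the arrays of a genotype biological replicates 1 and 2. Whether each came from 1 animal or a pool is not given in the sources used here, so p-values measure the spread between these preparations.

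The deposited values are summarised intensities per transcript cluster on a linear scale. Per the submitters' processing notes they were made with RMA, whose version is not given in the sources used here. RMA works on a log2 scale and includes a quantile step between arrays, while the deposited table is linear, so log2 of each deposited intensity was taken before any test, as the design allowed for. Array medians lay between 66.6 and 71.8, with upper quartiles between 208 and 234. In 8 cells of 8 clusters the value was a whole number over 100 times the median of the other arrays, about 1000 times its row; the table held 0 values with exactly 3 decimals, which points to a lost decimal separator, and these 8 cells were treated as missing. Dividing them by 1000, or keeping them as deposited, were alternatives. No column of the table lay outside the 8 arrays.

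Clusters were named through the platform annotation. Of 35512 clusters, 21789 had 1 gene symbol, 1621 had several and 12102 were listed with no gene. Through Entrez IDs, 21698 of the single-symbol clusters matched a mouse gene table of assembly GRCm38.p6, 91 did not, and 0 symbols changed; the table was used for names and for which genes are neighbours, and no coordinate is given. The planned removal of control clusters by an AFFX prefix removed 0 clusters, since the IDs are numbers, so clusters listed with no gene, which may include controls, stayed in the fit. Each gene was read on 1 cluster, the one with the highest mean over the 8 arrays among its single-symbol clusters; 999 of the 19938 genes had more than 1. No genome alignment or probe position was used, so cross-hybridisation between near-identical family members was not examined.

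All comparisons came from 1 linear model in limma 3.58.1 (R 4.3.3) on log2 intensities, with 1 mean per genotype over all 8 arrays and moderated variances with an intensity trend (4 residual and 3.976 prior degrees of freedom). Tests were two-sided, with Benjamini-Hochberg adjustment over all 35512 clusters and a threshold of adjusted p under 0.05. The comparisons were MIWI -/- and MIWI -/KI each against MIWI +/-, MIWI -/KI against MIWI +/KI, MIWI +/KI against MIWI +/-, MIWI -/KI against MIWI -/-, the mean of the differences without against with a wild-type allele, and the difference between those differences. Fold changes are differences of mean log2 intensity; SE is limma's moderated standard error, with a median of 0.172 for a difference between genotypes. For mean intensities the SD over 2 arrays is given.

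Lists of genes for spermatid functions, pathways and other cell types, 22 in all, were written before the data were examined, as were the model, the threshold, the alternatives and the rule for named genes. Some genes stand in more than 1 list. Lists were tested with limma's camera at its preset correlation of 0.01 on 1 cluster per gene, adjusted over the lists of a comparison, with camera at an estimated correlation and fry, which tests whether a list's genes move one way on balance, beside it. At the estimated correlation, the CREM target list was the 1 list that passed in MIWI -/- and in MIWI -/KI against MIWI +/- and without against with a wild-type allele, and no list passed in the other comparisons. Member counts were taken at the adjustment over all clusters and adjusted over the list alone.

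The rule for named genes took, among genes past the threshold whose arrays did not overlap between the groups, the 12 largest rises and the 12 largest falls of each mutant against MIWI +/- and the 6 largest of each for other comparisons, skipping symbols of uncharacterised loci. It skipped 1 riser and 4 fallers in MIWI -/-, 1 and 3 in MIWI -/KI against MIWI +/-, 1 and 1 against MIWI +/KI, 0 and 3 in MIWI +/KI against MIWI +/-, and 2 and 1 without against with a wild-type allele. Where no gene passed, the 5 smallest p values were named as values. Piwil1 was named throughout, with up to 4 members per list.

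Overlaps were set against the number that independent lists of the same sizes share, and for shared controls against 50 simulations of unchanged groups. The scripts were tested on simulated data. For MIWI -/- against MIWI +/- over 35512 clusters, limma called 36 of 67 clusters changed by 2-fold (53.7%), 67 of 67 changed by 4-fold and 66 of 66 changed by 8-fold, with 14 false calls. For MIWI -/KI against MIWI +/- over 19938 genes, camera called the 1 shifted list and 0 of 22 unshifted ones. In all simulated data genes were drawn independently of each other. False calls of camera that come from correlated genes were therefore not tested.

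Alternatives changed 1 choice at a time: quantile normalization, equal array medians, only clusters above the median level, no variance trend, robust variances, array weights, only the groups compared in the fit, a replicate block, a 2-fold minimum, the mean of a gene's clusters, and leaving out each array in turn, always 1 at a time. Added after the data were seen were the treatment of the 8 cells, only clusters listed with a gene, a crossed replicate block, and a term for MIWI +/KI replicates 1 and 2 and MIWI -/- replicate 2. Both MIWI +/KI arrays carry this term, so it is estimated only from the difference between the MIWI -/- arrays. In general that widens the standard errors of comparisons with MIWI +/KI. The labels give no batch, slide or scan date, so none was tested.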

Results

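Transcript levels were measured in purified round spermatids, the early haploid cells of sperm formation, from adult mouse testes. The 4 genotypes differed at Piwil1, the gene of MIWI, a PIWI protein that binds piRNAs in late meiotic and early haploid male germ cells. MIWI +/- carried a wild-type and a null allele, MIWI -/- only null alleles, MIWI +/KI a wild-type and a knock-in allele, and MIWI -/KI a null and a knock-in allele. The labels do not describe the knock-in allele further, and the series is about the catalytic activity of MIWI and the silencing of LINE1 retrotransposons. Each genotype had 2 arrays, labelled biological replicates, which makes 8 arrays of 35512 transcript clusters, 21789 of them with a single gene symbol and together naming 19938 genes. The deposited intensities had medians between 66.6 and 71.8 per array, and the number of arrays limits the precision of every value. Across clusters, log2 values of arrays of 1 genotype correlated with r between 0.970 and 0.995, and those of different genotypes with r between 0.960 and 0.989. The MIWI -/KI arrays were the pair with r = 0.970, below the r of 0.987 between MIWI -/KI replicate 1 and MIWI -/- replicate 2. MIWI -/KI replicate 1 also correlated more with MIWI +/KI replicate 1 (r = 0.9816) than with its own replicate. MIWI -/- replicate 2 correlated more with MIWI +/KI replicates 1 and 2 (r = 0.9855 and 0.9858) than with its own replicate (0.9836). The first principal component held 40.3% of the variance and set the 4 arrays without a wild-type allele apart from the 4 arrays with one. The second held 25.8% and did not. On it MIWI -/- replicate 2 and MIWI -/KI replicate 1 lay on the same side as MIWI +/KI replicates 1 and 2, with the other arrays opposite.

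Piwil1 itself was read on transcript cluster 10525961. Its mean intensity was 380 ± 12.8 (SD, n = 2) in MIWI +/-, 173 ± 31.5 (SD, n = 2) in MIWI -/-, 684 ± 17.2 (SD, n = 2) in MIWI -/KI and 714 ± 48.9 (SD, n = 2) in MIWI +/KI. No array of MIWI -/- overlapped an array of another genotype: the null arrays lay at 151 and 196, and the lowest of the others at 371. Against MIWI +/-, Piwil1 fell by 1.14 on the log2 scale in MIWI -/- (SE 0.17, adjusted p = 0.00771) and rose by 0.85 in MIWI -/KI (SE 0.17, adjusted p = 0.0275). Between the genotypes with a knock-in allele it differed by -0.06 (SE 0.17, adjusted p = 0.888). Where the probes lie relative to the part that the null allele lacks is not given in the sources used here, so the signal left in MIWI -/- neither checks nor contradicts its label. The fall in MIWI -/- missed the threshold without MIWI +/- replicate 1 (adjusted p = 0.0850) or replicate 2 (0.0727). The rise in MIWI -/KI missed it without MIWI +/- replicate 1 (0.163) or 2 (0.201), MIWI -/KI replicate 2 (0.0757), or MIWI +/KI replicate 1 (0.0819) or 2 (0.0823), with array weights (0.0906), and with only the groups compared in the fit (0.0809).

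**Figure D1:**
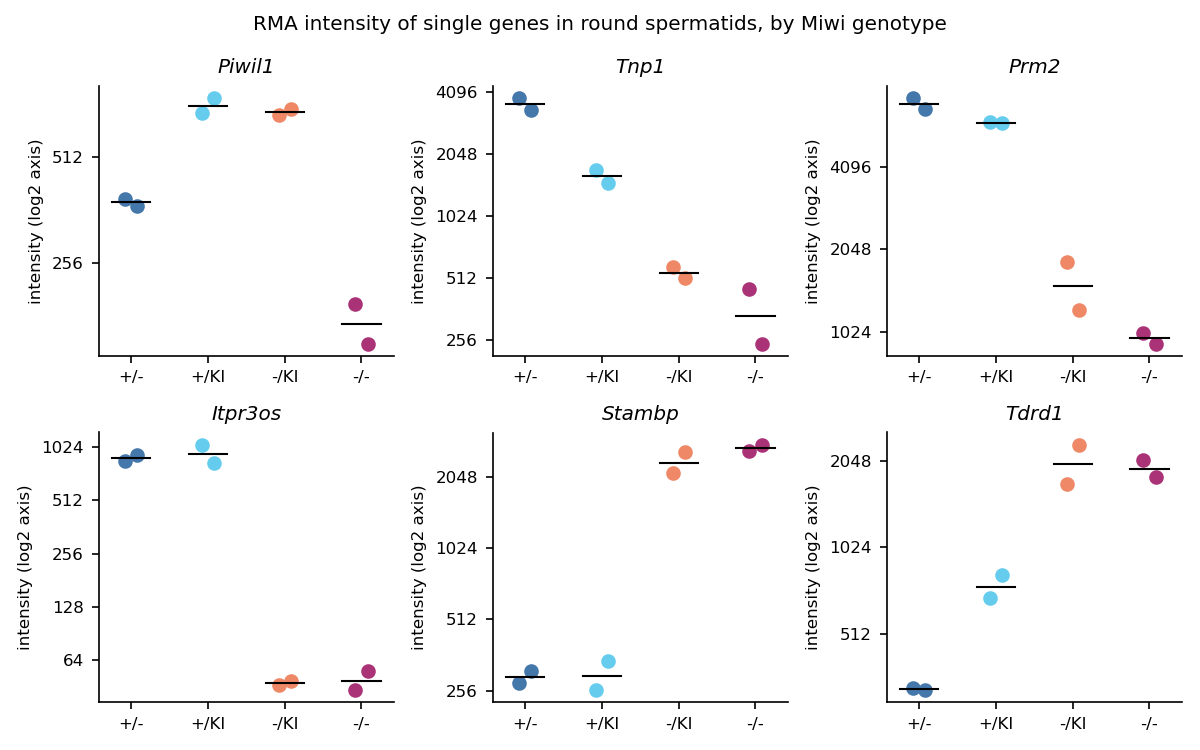
Deposited intensity, on a log2 axis, of Piwil1, Tnp1, Prm2, Itpr3os, Stambp and Tdrd1 in the 4 genotypes; points are arrays and bars are means of the log2 values of a genotype. The arithmetic mean of Tnp1 fell from 3577 in MIWI +/- to 542 in MIWI -/KI and 348 in MIWI -/-, while Piwil1 was lowest in MIWI -/-.

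The comparison of MIWI -/- with MIWI +/- asks what the loss of MIWI does to the spermatid transcriptome. The largest falls were in Acte1, an actin of the testis (log2 fold change -4.54, SE 0.16, 23.3-fold lower, adjusted p = 2.86e-05), in Bpifa3 (-4.43, SE 0.18, 21.6-fold) and in Tlcd4 (-4.35, SE 0.16, 20.4-fold), each with 2 arrays per genotype. Genes that package the haploid genome fell with them: Tnp1, which encodes a transition protein, by 10.7-fold (-3.43, SE 0.26), Tnp2 by 8.38-fold, and the protamine genes Prm2 by 7.19-fold and Prm1 by 7.09-fold. The largest rises were in Stambp, a deubiquitinase of endosomes (3.21, SE 0.18, 9.26-fold, adjusted p = 9.87e-05), in the protein kinase gene Prkx (3.01, SE 0.20, 8.06-fold) and in Lrrc61 (2.99, SE 0.17). Tdrd1, a Tudor-domain protein of the piRNA pathway, rose by 5.86-fold (2.55, SE 0.18) and Tex101, a germ cell surface glycoprotein, by 5.22-fold (2.38, SE 0.19). Further large falls were in Dydc2 (-4.34), Nudt16l2 (-4.32), the antisense transcript Itpr3os (-4.18), Tex37 (-4.12), the cystatin-like gene Cstl1 (-4.01), Lexm (-4.00), the kallikrein gene Klk1b8 (-3.96), Ubqlnl (-3.92) and the carbonic anhydrase gene Car2 (-3.90). Further large rises were in the magnesium transporter gene Slc41a1 (2.91), Lypd10 (2.46), Tmem106c (2.45), Fastkd1 (2.44), the pseudogene Cldn34-ps (2.35), the mannosidase gene Man2a2 (2.33) and Lypd11 (2.27). Lypd11, Lypd10 and Lrrc61 also stood higher in MIWI +/KI than in MIWI +/- (2.05, 1.81 and 1.74). In MIWI -/KI against MIWI +/KI they were not called (0.07, 0.55 and 0.76), while Stambp (2.98) and Fastkd1 (2.35) were. In all, 1222 of 19938 genes changed, 519 higher and 703 lower, and 688 of them by at least 2-fold, of which 475 were lower. The 1222 became 2044 with the mean of a gene's clusters and 584 with the term for MIWI +/KI replicates 1 and 2 and MIWI -/- replicate 2. Leaving out 1 array changed this count by over 1.5 times for 7 of the 8 arrays. It was 413 without MIWI +/- replicate 1, 375 without replicate 2, 2032 and 2043 without MIWI -/KI replicates 1 and 2. It was 656 and 654 without MIWI +/KI replicates 1 and 2, and 582 without MIWI -/- replicate 2.

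By gene list, the targets of CREM, the transcription factor that drives haploid gene expression, fell most clearly in MIWI -/-. Of 28 measured targets, 18 fell and 1 rose (22 and 1 adjusted over the list alone), with a median log2 fold change of -0.95. The list stood below the other genes (adjusted p = 2.74e-21 by limma's camera, adjusted p = 0.0231 with an estimated correlation). Of 22 genes of spermatid chromatin condensation, 9 fell and none rose (11 adjusted over the list alone; median -0.47, adjusted p = 9.69e-12, but adjusted p = 0.110 with an estimated correlation). Besides Tnp1, Tnp2, Prm1 and Prm2, these included Tssk6, a testis-specific kinase (-3.12). Among 37 genes of testis-specific kinases and signalling, 9 fell, also adjusted over the list alone, led by Tssk6, the protein kinase A subunit gene Prkar2a (-2.95), Camk4 (-1.65) and Tssk3 (-1.46). The list's adjusted p was 0.00213, and adjusted p = 0.241 with an estimated correlation. Haploid energy metabolism had 8 falls and 1 rise among 28 genes (9 and 2 adjusted over the list alone; adjusted p = 0.0168, and adjusted p = 0.241 with an estimated correlation). There the glycolytic gene Gapdhs (-1.30), the sodium pump gene Atp1a4 (-1.23) and Acsbg2 (-1.13) fell, and the transketolase-like gene Tktl2 (1.08) rose. Genes of sperm tail structure went both ways, with 9 falls and 3 rises among 35 (11 and 4 adjusted over the list alone): Spata18 (-2.07), the antizyme gene Oaz3 (-1.49), the anchoring protein gene Akap4 (-1.42) and Fscb (-1.11) fell. That list's median was 0.03 and its mean -0.17, and it did not pass as a whole (adjusted p = 0.0557). Of 24 sex-linked spermatid genes 4 fell (5 adjusted over the list alone), including Actrt1 (-2.00) and H2al3 (-1.50), with adjusted p = 0.00570, and adjusted p = 0.515 with an estimated correlation. Genes of the acrosome, which is built in the same cells, had 3 rises and no fall among 32 (6 rises and 1 fall adjusted over the list alone; adjusted p = 0.0746): Tex101 rose, as did Acr, the gene of the protease acrosin (0.77), and Ift20 (0.63). Single arrays mattered for several of these lists. Without MIWI +/- replicate 2, 11 CREM targets and 1 sex-linked gene fell, and 4 tail genes fell and none rose without either MIWI +/- replicate. No tail gene rose without MIWI -/- replicate 2. Falls in energy metabolism numbered 2 and 1 without MIWI +/- replicates 1 and 2, 4 without either MIWI +/KI replicate, and 5 and 4 without MIWI -/- replicates 1 and 2. The energy list lost its call without MIWI +/- replicate 1 (adjusted p = 0.0563) or MIWI -/- replicate 2 (adjusted p = 0.127), and the sex-linked list without MIWI -/- replicate 2 (adjusted p = 0.172). Acrosome rises numbered 6 without either MIWI -/KI replicate and 1 when any 1 of MIWI +/- replicates 1 and 2, MIWI +/KI replicates 1 and 2 and MIWI -/- replicate 2 was left out.

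Within the piRNA pathway 5 of 31 genes rose in MIWI -/- and none fell, the same count as adjusted over the list alone. They included Tdrd1, Morc1, a gene needed for retrotransposon silencing in male germ cells (1.80, SE 0.17), Piwil2, which encodes the PIWI protein MILI (0.99, SE 0.14), and Henmt1, the methyltransferase of piRNA ends (0.86, SE 0.15). The list's adjusted p was 0.0432, and adjusted p = 0.723 with an estimated correlation. That call was lost without MIWI -/KI replicate 1 (adjusted p = 0.0639) or 2 (0.0664), MIWI +/- replicate 2 (0.0690) or MIWI -/- replicate 1 (0.535). The 5 rises became 2 without either MIWI +/- replicate and 3 without either MIWI +/KI replicate or MIWI -/- replicate 1. Of 43 genes of germ cell mRNA storage and translation control, Ago2 (1.02) and Elavl1 (0.85) rose and the decapping gene Dcp1a fell (-1.13), without a shift of the list (3 rises and 2 falls adjusted over the list alone; adjusted p = 0.116). The list of genes of or derived from retrotransposons had 8 measured members and no called gene in either adjustment. Its median was -0.01 (camera adjusted p = 0.903). Peg10 (-0.33) and Pgbd1 (0.22) were among the members, although Pgbd1 derives from a DNA transposon and not from a retrotransposon. LINE1 itself is no named gene of the table. Interferon and nucleic acid sensing had a median of -0.02 over 36 genes (adjusted p = 0.903), with 1 fall, in the chemokine gene Ccl5 (-0.95), in both adjustments. Among 36 stress and immediate early genes Herpud1, a gene of the endoplasmic reticulum stress response (-2.85), Srxn1 (-0.94) and Asns (-0.78) fell, 3 in both adjustments, and the list did not shift (adjusted p = 0.565). Of 32 genes of the p53 and DNA damage response, Gadd45b (1.48) and Zmat3 (1.19) rose (3 rises and 2 falls adjusted over the list alone; adjusted p = 0.116). For the 3 lists of general cell functions, the adjusted p was 0.0903 for ribosomal proteins, where Rpl10a rose (1.61), and 0.903 for both the mitochondrial respiratory chain, with no called gene, and the ubiquitin and proteasome list, where 2 genes rose and 3 fell. Those 3 falls became 1 without either MIWI +/KI replicate or MIWI -/- replicate 2, and none without either MIWI +/- replicate. List-alone adjustment gave the same counts in these 3 lists.

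Markers of other testicular cells were measured to follow what else the gradient fractions held. In MIWI -/-, 3 of 32 Sertoli cell markers fell, Cst12 (-1.31), Aard (-1.14) and Tsx (-0.88), against 6 adjusted over the list alone, and the list's median was -0.28 (adjusted p = 5.16e-05, and adjusted p = 0.515 with an estimated correlation). No Sertoli marker passed when any 1 of MIWI +/- replicates 1 and 2, MIWI +/KI replicates 1 and 2 and MIWI -/- replicate 2 was left out, and 5 fell when any 1 of the other arrays was. The 35 spermatocyte markers had 1 rise, in Piwil2, and 1 fall, in Syce2 (-1.49), in both adjustments (adjusted p = 0.434). Among 26 blood and macrophage markers Aif1 (-1.10), Alas2 (-0.92) and H2-Aa (-0.73) fell (3 in both adjustments), and the list's adjusted p was 0.116. Of 30 peritubular, vascular and stromal markers, the smooth muscle actin genes parted in both adjustments (camera adjusted p = 0.171 for the list). Actg2 fell by 6.10-fold (-2.61) and Acta2 rose by 1.61-fold (0.68). Which cells gave the Actg2 signal was not examined, so its fall is no measure of muscle cells in the fractions. Lin28a (0.77) was the 1 spermatogonia marker of 30 that rose, with none adjusted over the list alone (adjusted p = 0.660), and no Leydig cell marker of 22 passed in either adjustment (adjusted p = 0.268).

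MIWI -/KI against MIWI +/- asks what the knock-in allele does as the only allele that is not null. Itpr3os fell by 18.7-fold (-4.22, SE 0.19, adjusted p = 7.35e-05) and Bpifa3 by 14.0-fold (-3.80, SE 0.18), each with 2 arrays per genotype, and Nudt16l2 stood at -4.00 (SE 0.25). Stambp rose by 8.01-fold (SE 0.18 on the log2 scale), Prkx by 7.61-fold (2.93, SE 0.20), Fastkd1 by 6.93-fold (2.79, SE 0.26) and Tdrd1 by 6.06-fold (2.60, SE 0.18). Tnp1 fell by 6.59-fold (-2.72, SE 0.26), Prm2 by 4.62-fold, Prm1 by 4.44-fold and Tnp2 by 4.37-fold. Further falls were in Dydc2 (-3.80), Klk1b8 (-3.69), Acte1 (-3.61), Klk1b5 (-3.59), Tlcd4 (-3.53), Tex37 (-3.50), Efcab1 (-3.48), Lexm (-3.47) and Car2 (-3.42). Further rises were in Lrrc61 (2.50), Tex101 (2.45), Slc41a1 (2.42), the deubiquitinase gene Usp51 (2.37), Lypd10 (2.36), the stress-inducible gene Gadd45b (2.34), the protease gene Asprv1 (2.33) and Hmmr, which acts at the mitotic spindle (2.32). Lrrc61 and Lypd10 were not called against MIWI +/KI. Here 1243 genes changed, 621 higher and 622 lower, and 708 of them by at least 2-fold. The count was 361 and 344 without MIWI +/- replicates 1 and 2, 2775 without MIWI -/KI replicate 1, 682 and 679 without MIWI +/KI replicates 1 and 2, 715 with array weights and 487 with only the groups compared in the fit.

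CREM targets fell in MIWI -/KI as well, 18 of 28 with no rise (21 and 1 adjusted over the list alone; median -0.93, adjusted p = 9.21e-18, adjusted p = 0.0327 with an estimated correlation). Chromatin condensation had 9 falls among 22 (10 adjusted over the list alone), led by Tssk6 (-3.26) and Gm614 (-3.11), with adjusted p = 2.77e-09 and adjusted p = 0.167 with an estimated correlation. Testis-specific kinases and signalling had 9 falls among 37 (9 and 1 rise adjusted over the list alone), among them Prkar2a (-2.86), Tssk3 (-1.56) and Camk4 (-1.21). That list's median was 0.02 and its mean -0.31 (adjusted p = 0.0228, and adjusted p = 0.315 with an estimated correlation). The piRNA pathway had 5 rises among 31 genes (5 and 1 fall adjusted over the list alone): Tdrd1, Morc1 (2.07), Piwil2 (1.03) and Henmt1 (0.80) were among them, with a median of 0.19 (adjusted p = 0.000240, and adjusted p = 0.427 with an estimated correlation). The p53 and DNA damage list rose on balance (median 0.21, adjusted p = 0.0165, and adjusted p = 0.216 with an estimated correlation), with rises of Gadd45b and Sesn1 (0.74) and a fall of Tnfrsf10b (-0.63), against 8 rises and 2 falls adjusted over the list alone. Sertoli cell markers had 5 falls among 32 (11 adjusted over the list alone; median -0.36, adjusted p = 3.07e-07, and adjusted p = 0.392 with an estimated correlation), including Cst12 (-1.25), Aard (-1.17), Defb19 (-1.12) and Tsx (-1.02). Spermatocyte markers lay higher, with a median of 0.21 (adjusted p = 0.0184, and adjusted p = 0.662 with an estimated correlation). Both marker shifts moved with MIWI -/KI replicate 2, whose median deviation from each gene's mean over the 8 arrays was 0.42 for spermatocyte markers and -0.38 for Sertoli cell markers. Without that array no Sertoli marker passed, the spermatocyte list had a median of -0.000279 (adjusted p = 0.773), and the piRNA and p53 lists lost their calls (both with adjusted p = 0.0843). Sertoli falls numbered 9 without MIWI -/KI replicate 1, 1 without either MIWI +/KI replicate and none without either MIWI +/- replicate. Without MIWI +/- replicates 1 and 2, 9 and 8 CREM targets and 4 and 3 kinase and signalling genes fell. That last list lost its call without MIWI -/KI replicate 1 (adjusted p = 0.370), where 10 piRNA pathway genes rose, against 3 and 2 without MIWI +/- replicates 1 and 2 and 3 without either MIWI +/KI replicate.

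MIWI -/KI against MIWI +/KI gives the effect of lacking a wild-type allele beside a knock-in allele, and shares no array with MIWI -/- against MIWI +/-. Itpr3os fell by 19.8-fold (-4.30, SE 0.19, adjusted p = 0.000557), the kallikrein gene Klk1b5 by 11.1-fold (-3.47, SE 0.23) and the phosphatase gene Phospho1 by 7.59-fold (-2.92, SE 0.21), with 2 arrays per genotype. Mlkl, the effector of necroptosis (-2.77), Bpifa3 (-2.76) and Tlcd4 (-2.74) followed. Stambp rose by 7.91-fold (2.98, SE 0.18), the transferrin receptor gene Tfrc by 5.91-fold (2.56, SE 0.24), Fastkd1 by 5.08-fold (2.35, SE 0.26) and Morc1 by 4.60-fold (2.20, SE 0.17). So did the zinc finger gene Zfp729b by a log2 of 2.32 (SE 0.37) and the exocyst gene Exoc6 by 4.90-fold (2.29, SE 0.27). Tfrc was not called in MIWI -/- against MIWI +/- (0.66, SE 0.24, limma adjusted p = 0.211). Prm2 fell by 3.95-fold and Tnp1 by 2.95-fold. In total 485 genes changed, 227 higher and 258 lower, and 334 by at least 2-fold. The number was 1384 with the mean of a gene's clusters, 1100 over clusters listed with a gene and 909 above the median level. It was 0 with the term for MIWI +/KI replicates 1 and 2 and MIWI -/- replicate 2. The count was 196 without MIWI +/- replicate 1 or without replicate 2, 2664 and 254 without MIWI -/KI replicates 1 and 2, 42 and 45 without MIWI +/KI replicates 1 and 2, 252 with array weights and 100 with only the groups compared in the fit. Without MIWI +/KI replicate 1, Tfrc (adjusted p = 0.0554), Fastkd1 (0.0938), Zfp729b (0.223) and Exoc6 (0.102) lost their calls, and without replicate 2 Fastkd1 (0.0686), Zfp729b (0.171) and Exoc6 (0.0977) did. Zfp729b also did without MIWI +/- replicate 1 (0.0505) or, by a narrow margin, 2.

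Among the lists, 10 of 28 CREM targets fell in MIWI -/KI against MIWI +/KI (16 falls and 2 rises adjusted over the list alone; median -0.53, adjusted p = 2.92e-08, and adjusted p = 0.137 with an estimated correlation). Of the chromatin condensation genes 7 of 22 fell (9 adjusted over the list alone; adjusted p = 0.000174, and adjusted p = 0.463 with an estimated correlation). In the piRNA pathway Morc1, Tdrd1 (1.41) and Piwil2 (0.74) rose (9 rises and 1 fall adjusted over the list alone; median 0.34, adjusted p = 4.59e-07, and adjusted p = 0.519 with an estimated correlation). Gadd45b (2.00), Sesn1 (0.95) and Pmaip1 (0.80) rose among the p53 and DNA damage genes, 3 in both adjustments (adjusted p = 0.0471, and adjusted p = 0.463 with an estimated correlation). Peg10 fell (-1.19), the 1 gene of its list to pass in both adjustments (adjusted p = 0.153 for the list). Shifts without many called members were those of ribosomal proteins (median 0.26), the respiratory chain (0.31), the proteasome list (0.38), spermatocyte markers (0.35), Leydig cell markers (0.31), sex-linked genes (0.29), Sertoli cell markers (-0.29) and stress genes (-0.17). None of these 8 passed with an estimated correlation, where the respiratory chain had adjusted p = 0.573 and ribosomal proteins adjusted p = 0.604. With a term for MIWI +/KI replicates 1 and 2 and MIWI -/- replicate 2, the ribosomal (median -0.33, adjusted p = 1.47e-08), respiratory (-0.24, adjusted p = 0.000469), Leydig (-0.09, 0.0999) and sex-linked (-0.06, 0.137) shifts turned. The spermatocyte median shrank to 0.09 (adjusted p = 0.993), the proteasome median to 0.03 and the stress median to -0.0084, while the Sertoli median went to -0.50. No CREM target or chromatin gene was called with that term, with medians of -0.44 and -0.52, against -0.53 and -0.14 without it. When either MIWI +/KI replicate was left out, 1 CREM target and 2 chromatin genes fell, and 5 CREM targets fell without MIWI -/KI replicate 2 or either MIWI +/- replicate. The piRNA rises numbered 10 without MIWI -/KI replicate 1 and 1 without either MIWI +/KI replicate, and those of p53 genes 7 without MIWI -/KI replicate 1 and 1 without MIWI -/KI replicate 2, either MIWI +/KI or either MIWI +/- replicate. Without MIWI -/KI replicate 2 calls were lost by the spermatocyte (adjusted p = 0.592), sex-linked (0.423), Leydig (0.306), p53 (0.239) and stress (0.120) lists, and without MIWI -/KI replicate 1 by ribosomal proteins (0.0666) and stress genes (0.0556). The Leydig list also lost its call without MIWI +/KI replicate 1 (0.238), and the p53 list without MIWI +/KI replicate 1 (0.0675), MIWI +/- replicates 1 (0.0548) and 2 (0.0544) or MIWI -/- replicates 1 (0.0554) and 2 (0.0558).

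The effects of lacking a wild-type allele were then compared between the null and the knock-in background. Of the 1222 genes changed in MIWI -/- against MIWI +/- and the 485 changed in MIWI -/KI against MIWI +/KI, 354 changed in the same direction in both, 129 higher and 225 lower, against 15.01 that independent lists of these sizes would share, and 1 in opposite directions. Both lists came from the same fit, with 1 variance per gene over all arrays, which favours genes of low variance in both. Without either MIWI +/- replicate, which lie outside MIWI -/KI against MIWI +/KI, the 485 became 196. The lists of these comparisons are therefore not independent, and 15.01, like the 38.1 below, is no exact measure of chance. The log2 fold changes of these comparisons, which have no array in common, correlated across genes with r = 0.487, where simulated unchanged groups gave -0.000408; genes are not independent replicates. The 354 shared genes became 150 and 147 without MIWI +/- replicates 1 and 2, 764 and 235 without MIWI -/KI replicates 1 and 2, and 42 and 44 without MIWI +/KI replicates 1 and 2. With the term for MIWI +/KI replicates 1 and 2 and MIWI -/- replicate 2, MIWI -/KI against MIWI +/KI had no called gene, so the overlap was 0. MIWI -/- and MIWI -/KI, both against MIWI +/-, shared 922 genes in the same direction (371 higher, 551 lower) against 38.1 for independent lists, with 1 opposite. The 922 became 309 and 290 without MIWI +/- replicates 1 and 2, 524 and 522 without MIWI +/KI replicates 1 and 2, and 556 without MIWI -/- replicate 2. The fold changes of these mutants correlated with r = 0.886, and simulated unchanged groups against the shared controls gave 0.499. The covariance was 0.174 against 0.0174 in the simulation, a difference of 0.157, and part of any excess in shared genes may come from the 2 shared control arrays, which are too few to split.

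**Figure D2:**
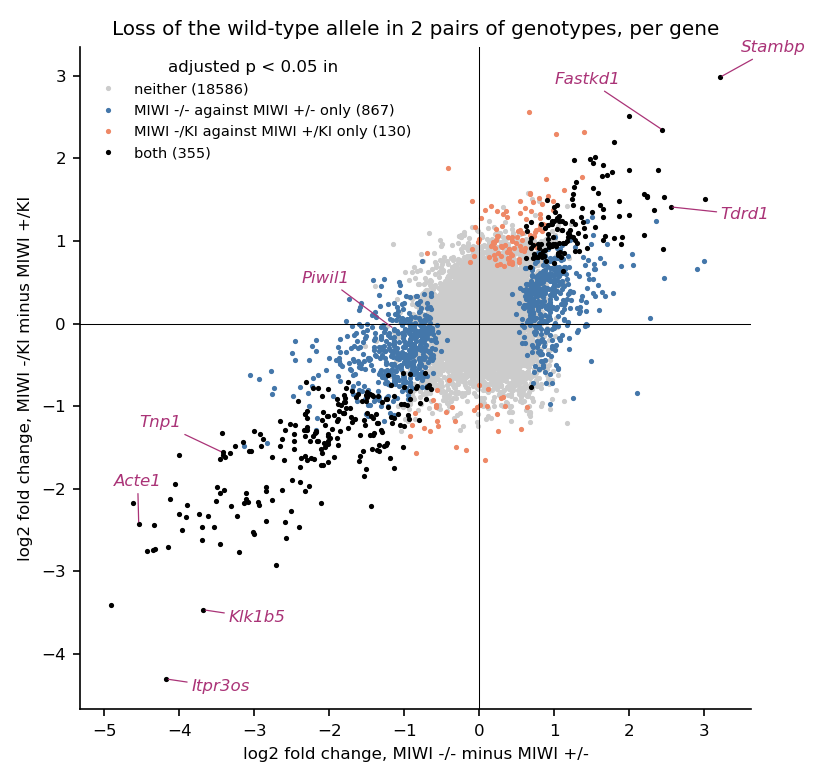
Log2 fold change of each gene in MIWI -/- against MIWI +/- (horizontal axis) and in MIWI -/KI against MIWI +/KI (vertical axis). Black points are the 355 genes called in both, 1 of them in opposite directions. Blue and orange points are the 867 and 130 called only in the first or the second comparison, and grey points the others. Itpr3os lies at -4.18 and -4.30, and Stambp at 3.21 and 2.98.

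MIWI +/KI against MIWI +/- compares a knock-in with a null allele beside a wild-type one. Lypd11 rose by 4.13-fold (2.05, SE 0.19), Lypd10 by 3.50-fold (1.81, SE 0.21), Lrrc61 by 3.34-fold (1.74, SE 0.17), Tmem106c by 2.51-fold (1.33, SE 0.14) and Tkfc by 1.96-fold (0.97, SE 0.11). Smim23 (-1.72, SE 0.20), the tubulin polymerization gene Tppp2 (-1.71, SE 0.17), Tex55 (-1.69, SE 0.18), the chitinase-like gene Chil3 (-1.62, SE 0.19), the acetylcholine receptor gene Chrna5 (-1.61, SE 0.18) and Tex50 (-1.37, SE 0.15) fell. In total 19 genes changed, 5 higher and 14 lower, at adjusted p of 0.0444 for 10 of these 11 genes and 0.0457 for Chil3. All 19 also changed in the same direction in MIWI -/- against MIWI +/-, a comparison that shares the MIWI +/- arrays. The covariance of the 2 comparisons was 0.0900 against 0.0174 in simulated unchanged groups, where arrays were drawn independently. Across genes, however, MIWI -/- replicate 2 minus replicate 1 correlated with MIWI +/KI minus MIWI +/- (r = 0.52). A deviation common to these arrays can add to the covariance, which therefore cannot separate it from an effect of genotype. The count depends on the setting: no gene passed limma's threshold without either array of MIWI +/-, MIWI +/KI or MIWI -/-, after quantile normalization or with equal array medians, while 2335 genes had an unadjusted p under 0.05 in the fit of all 8 arrays. Other settings gave more: 26 and 27 without MIWI -/KI replicates 1 and 2, 120 above the median level, 193 over clusters with a gene, 362 with the mean of a gene's clusters, 1474 with only the groups compared in the fit and 1799 with array weights.

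No member of any list passed over all genes in MIWI +/KI against MIWI +/-. Ribosomal proteins (median -0.34, adjusted p = 3.75e-11) and the respiratory chain (-0.30, adjusted p = 1.60e-08) stood below the other genes, but adjusted p = 0.483 and adjusted p = 0.512 with an estimated correlation. No ribosomal or respiratory gene passed adjusted over the list alone. CREM targets (-0.28, adjusted p = 5.26e-10; 8 falls and 1 rise adjusted over the list alone) and chromatin condensation genes (-0.52, adjusted p = 1.50e-07; 7 falls adjusted over the list alone) did so too, with adjusted p = 0.102 and adjusted p = 0.137 with an estimated correlation. The other 6 called lists stood lower as well: sex-linked genes (-0.36, adjusted p = 9.62e-07), the proteasome list (-0.22, 1.32e-05), testis-specific kinases (-0.19, 3.43e-05), energy metabolism (-0.21, 0.00412), sperm tail (-0.16, 0.0120) and Sertoli cell markers (-0.08, 0.0482). With an estimated correlation their adjusted p lay between 0.137 and 0.717. Without MIWI +/- replicate 1 the tail (adjusted p = 0.0667), energy (0.0582) and Sertoli (0.271) lists lost their calls. The Sertoli list also did without MIWI -/KI replicate 1 (0.0882) or 2 (0.0885) or MIWI +/KI replicate 1 (0.576). Tnp1 stood at -1.16 (SE 0.26, adjusted p = 0.163), Tnp2 at -0.59 and Prm2 at -0.23. The ribosomal and respiratory lists also differed between replicates, replicate 2 lying below replicate 1 in every genotype. The medians were -0.58 and -0.57 in MIWI -/-, -0.22 and -0.29 in MIWI -/KI, -0.10 and -0.21 in MIWI +/-, and -0.09 and -0.11 in MIWI +/KI. A term for MIWI +/KI replicates 1 and 2 and MIWI -/- replicate 2 was chosen after the data were seen. These arrays lie low together on the ribosomal and respiratory lists, and the term is estimated from the MIWI -/- pair alone. In a fit with it, the signs of both lists turned in this comparison (camera adjusted p = 1.02e-05 and 3.07e-06), which is therefore no independent test. The signs of the proteasome (0.0171) and Sertoli (0.186) lists turned too. The energy metabolism median went from -0.21 to 0.02, and the sex-linked median from -0.36 to -0.0068. In that fit 0 genes were called by limma, with 484 at an unadjusted p under 0.05. There Tnp1 stood at -0.28 (SE 0.25) and Prm2 at -0.10, and the median was -0.10 for chromatin condensation genes and -0.22 for CREM targets.

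MIWI -/KI against MIWI -/- is the direct test of a knock-in against a second null allele. No gene passed limma's threshold, with 908 genes, 4.55% of those tested, at an unadjusted p under 0.05. The 908 became 210 with only the groups compared in the fit, 328 with array weights and 1217 with the mean of a gene's clusters. It also moved, in both directions, when single arrays were left out. The genes with the smallest p were Piwil1, 1.99 higher in MIWI -/KI (SE 0.17, 3.98-fold, adjusted p = 0.0816), 3110040M04Rik (1.51, SE 0.15, adjusted p = 0.0818), and Rpa1, a subunit of the single-strand DNA binding protein (1.92, SE 0.19, adjusted p = 0.0818). They were followed by the exocyst gene Exoc8 (1.32, SE 0.17, adjusted p = 0.235) and Naaladl2 (1.86, SE 0.27, adjusted p = 0.536). Without MIWI -/KI replicate 1, 6 genes passed, among them Piwil1, 3110040M04Rik, Rpa1 and Naaladl2 (each with adjusted p = 0.0437), and 3 genes passed when only clusters above the median level were tested. Prm2 stood at 0.64 and Tnp2 at 0.94, both with adjusted p = 0.998. CREM targets had a median of 0.14 (adjusted p = 0.00113, and adjusted p = 0.616 with an estimated correlation), with 1 rise adjusted over the list alone. Without MIWI -/KI replicate 1 that list had adjusted p = 0.0599 and chromatin condensation adjusted p = 0.0781. Sex-linked genes (0.24), spermatocyte markers (0.20), the proteasome list (0.13), chromatin condensation (0.12) and the piRNA pathway (0.09) were called with the preset correlation only, all with an estimated correlation at adjusted p = 0.717 or 0.767. Of these, all lost their calls when 1 array was left out. Without MIWI -/- replicate 2 the adjusted p was 0.972 for the spermatocyte list (median 0.03), 0.222 for the proteasome list, whose median turned to -0.06, 0.972 for the piRNA pathway and 0.706 for chromatin condensation and sex-linked genes. Without MIWI -/KI replicate 2 it was 0.0536 for the spermatocyte list, whose median turned to -0.07, and 0.775 for the piRNA pathway (median 0.02), the proteasome list and sex-linked genes.

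Over both backgrounds, the 4 arrays without a wild-type allele were set against the 4 with one. Itpr3os (-4.24, SE 0.13, 18.9-fold, adjusted p = 8.94e-06), Bpifa3 (-3.59, SE 0.12), Klk1b5 (-3.57, SE 0.16), Tlcd4 (-3.55, SE 0.12), Nudt16l2 (-3.53, SE 0.18) and Acte1 (-3.48, SE 0.12) fell most. Stambp (3.10, SE 0.13, 8.56-fold, adjusted p = 1.44e-05), Fastkd1 (2.39, SE 0.18), Prkx (2.26, SE 0.14), Tex101 (2.12, SE 0.14), Morc1 (2.00, SE 0.12) and Tdrd1 (1.98, SE 0.13) rose most. Of the CREM targets 18 of 28 fell with no rise (21 falls and 3 rises adjusted over the list alone; median -0.72, adjusted p = 2.52e-17, adjusted p = 0.0343 with an estimated correlation). Other members of fixed lists that changed included Herpud1 (-2.62), Actg2 (-2.13), Gadd45b (1.74), Syce2 (-1.15), Acta2 (0.96) and the proteasome genes Psmb1 (0.86) and Psma8 (0.75). The proteasome list had 7 rises and 2 falls among 41 genes (10 and 3 adjusted over the list alone; median 0.24, adjusted p = 0.00125, and adjusted p = 0.558 with an estimated correlation). Sertoli cell markers had 5 falls among 32 (11 adjusted over the list alone; median -0.29, adjusted p = 7.60e-07, and adjusted p = 0.378 with an estimated correlation). Sertoli falls numbered 13 and 3 without MIWI -/KI replicates 1 and 2, 2 without MIWI -/- replicate 2, 1 and 0 without MIWI +/KI replicates 1 and 2, and 0 and 1 without MIWI +/- replicates 1 and 2. The proteasome list lost its call without MIWI -/- replicate 1 (adjusted p = 0.0855, with 3 rises), and had 1 rise when any 1 of the 4 arrays with a wild-type allele was left out. Chromatin condensation genes had 9 falls among 22 (11 adjusted over the list alone; median -0.40, adjusted p = 1.24e-08, and adjusted p = 0.189 with an estimated correlation). The other 6 called lists stood higher: the piRNA pathway (median 0.17, adjusted p = 2.07e-05), the respiratory chain (0.15, 0.00339), spermatocyte markers (0.18, 0.00910), acrosome genes (0.13, 0.0211), p53 genes (0.12, 0.0364) and Leydig cell markers (0.28, 0.0387). With an estimated correlation their adjusted p lay between 0.363 and 0.620. Without MIWI -/- replicate 1 the acrosome (adjusted p = 0.0987), spermatocyte (0.123), Leydig (0.206), p53 (0.0598) and respiratory (0.587) lists lost their calls. The spermatocyte (0.345), Leydig (0.193) and p53 (0.107) lists did so without MIWI -/KI replicate 2, the Leydig (0.0514) and respiratory (0.0860) lists without MIWI -/KI replicate 1, and the Leydig list without MIWI +/KI replicate 1 (0.110). In total 1647 genes changed, 864 higher and 783 lower, of which 449 by at least 2-fold, 150 higher and 299 lower. The count was 798 and 775 without MIWI +/- replicates 1 and 2, 654 and 712 without MIWI +/KI replicates 1 and 2, and 3298 without MIWI -/KI replicate 1.

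**Figure D3:**
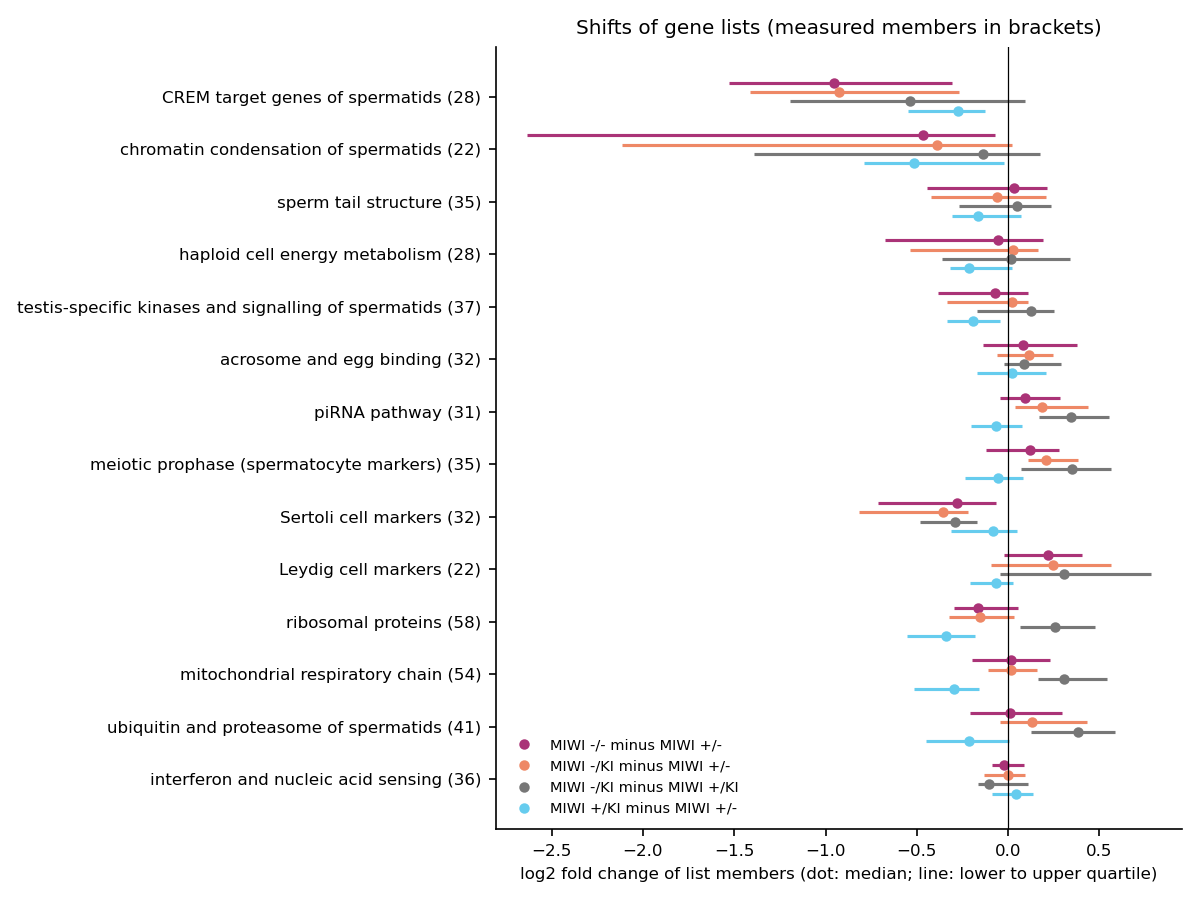
Median log2 fold change (dot) of 14 of the gene lists in 4 comparisons, with lines from the lower to the upper quartile of their genes and measured members in brackets. The CREM targets lie at -0.95 in MIWI -/- and -0.93 in MIWI -/KI against MIWI +/-, and the acrosome genes at 0.08 and 0.12.

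Whether the lack of a wild-type allele acted differently beside a knock-in and beside a null allele was tested as the difference of the differences. No named gene passed limma's threshold in the fit of all 8 arrays, and 2585 genes had an unadjusted p under 0.05. With the term for MIWI +/KI replicates 1 and 2 and MIWI -/- replicate 2 that number was 435, and it also moved when single arrays were left out. Other settings did call genes: 590 with the mean of a gene's clusters, 279 over clusters listed with a gene and 173 above the median level. The smallest p values belonged to Tex55 (2.43, SE 0.25), Gm136 (2.44, SE 0.26), Lrrc61 (-2.23, SE 0.24), Tex50 (2.01, SE 0.22) and Acte1 (2.12, SE 0.23), all with adjusted p = 0.0711. In the null background Acte1 stood at -4.54. MIWI +/KI against MIWI +/- already had Acte1 at -1.19, Gm136 at -1.66, Tex55 at -1.69 and Lrrc61 at 1.74. A shifted MIWI +/KI control thus enters these differences. CREM targets differed by a median of 0.44 between the backgrounds (adjusted p = 2.29e-08, 14 higher and 1 lower adjusted over the list alone, and adjusted p = 0.134 with an estimated correlation). Chromatin condensation genes differed by 0.72 (adjusted p = 4.01e-07, 8 higher adjusted over the list alone, and adjusted p = 0.228 with an estimated correlation). With the term for MIWI +/KI replicates 1 and 2 and MIWI -/- replicate 2, the median difference was 0.40 for CREM targets and 0.22 for chromatin condensation genes. Without MIWI -/- replicate 1, 241 genes were called, and without MIWI -/KI replicate 1, 48. The 5 genes named here passed in both cases, with adjusted p of 0.0381 or 0.0386 in the first and 0.0462 or 0.0496 in the second.

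**Figure D4:**
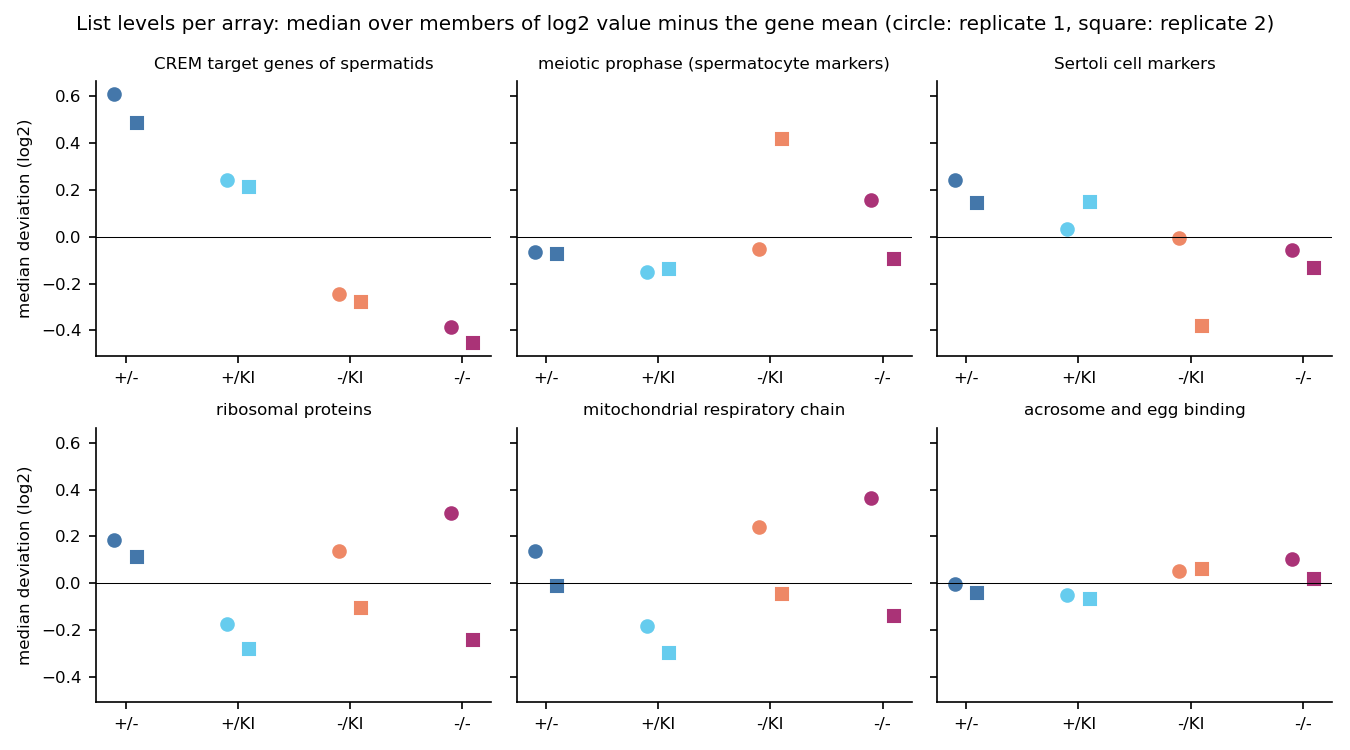
Median over a list's genes of the log2 value minus the gene's mean over the 8 arrays, for 6 lists per array; circles are replicate 1 and squares replicate 2. MIWI -/KI replicate 2 is highest for spermatocyte markers, at 0.42, and lowest for Sertoli cell markers, at -0.38.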

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

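The comparisons of lists and transcript clusters and the tests of splits of the arrays were planned; the other tests in this part, and the term for 3 arrays, were chosen only after the results were seen. Each result here is a difference between the null and the knock-in background in the effect of lacking a wild-type allele. With limma's camera at its preset correlation, 8 lists were less reduced, or higher, in the knock-in background. The same difference is MIWI -/KI against MIWI -/- minus MIWI +/KI against MIWI +/-. Chromatin condensation medians in these were 0.12 and -0.52, CREM target medians 0.14 and -0.28, and ribosomal medians 0.03 and -0.34. For all 8 lists the second was larger in size, so much of the difference lies in a lower MIWI +/KI control. The median difference was 0.44 for CREM targets (adjusted p = 2.29e-08, and adjusted p = 0.134 with an estimated correlation), 0.72 for chromatin condensation (4.01e-07, and 0.228), 0.71 for sex-linked genes (4.01e-07, and 0.276), 0.34 for testis-specific kinases (0.000126, and 0.228) and 0.26 for haploid energy metabolism (0.0202, and 0.240; lost without MIWI +/- replicate 1 at 0.107, MIWI -/KI replicate 2 at 0.0506, MIWI +/KI replicate 2 at 0.0534 and MIWI -/- replicate 2 at 0.113). For general functions it was 0.42 for ribosomal proteins (7.00e-06, and 0.752), 0.36 for the respiratory chain (0.000113, and 0.752) and 0.37 for the proteasome list (7.61e-06, and 0.569); without MIWI -/- replicate 2 the first was 0.172 and the second 0.378, and without MIWI -/KI replicate 1 the second was 0.0568. With the term for MIWI +/KI replicates 1 and 2 and MIWI -/- replicate 2, the last 3 turned, to -0.43 (1.45e-12), -0.43 (9.04e-12) and -0.13 (0.0223). The others then stood at 0.40 for CREM targets, 0.22 for chromatin condensation, 0.08 for sex-linked genes, 0.21 for kinases and -0.00438 for energy metabolism. One unnamed transcript cluster, 10340088, differed by -2.15 (limma adjusted p = 0.0461), with log2 values of 5.37 and 5.38 in the MIWI +/KI arrays and between 3.79 and 4.60 in the other arrays.

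CREM targets were lower without a wild-type allele, with a median of -0.72. Fitted as 2 groups, the split of the 8 arrays by wild-type allele gave 1263 changed genes. The highest of the other 34 splits gave 3. Only 1 of 35 splits was as large, but 1 of 35 is the smallest share these splits can give. Every other split puts arrays with and without a wild-type allele in 1 group, which widens the spread within groups. Their low counts therefore do not measure chance, which this test cannot exclude. Dilution of spermatid RNA by RNA of cells without acrosome transcripts would lower the acrosome list too, but its lower quartile stood at -0.0224. Spermatocyte markers stood higher, with a median of 0.18. Whether spermatocytes hold acrosome transcripts was not examined, so this list cannot decide on dilution by those cells. Fewer later-step spermatids among the collected cells could give such falls: the CREM targets of the highest array without a wild-type allele lay 0.46 below those of the lowest array with one, and because cell stage and genotype change together here, this cannot be told apart from a lower level per cell. Loss of late cells with unchanged levels in the rest would raise all transcripts that those cells lack by 1 factor. The upper quartile of the spermatocyte markers rose by 0.29, which is less than 2-fold. Signal near background can shrink such a rise, and transcripts particular to early round spermatids were not tested. The markers therefore cannot decide this for the genes at least 2-fold higher.

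Ribosomal and respiratory chain transcripts were lower in MIWI +/KI than in MIWI +/-, with medians of -0.34 and -0.30. An effect of the knock-in allele that needs no wild-type allele cannot be told apart from other explanations. In MIWI -/KI against MIWI -/- the lower quartile of the ribosomal list was -0.12, above -0.34, but without MIWI -/- replicate 2 its median was -0.23 and its lower quartile -0.39, so that array decides the outcome. A difference between arrays other than genotype is a candidate explanation, since MIWI -/- replicate 2 minus replicate 1, of the same genotype, correlated with the first comparison across 19933 genes with r = 0.52, while the MIWI -/KI replicates gave r = -0.13. On the ribosomal and respiratory lists alone, replicate 2 lay below replicate 1 in MIWI -/KI too, by medians of -0.22 and -0.29, against -0.58 and -0.57 in MIWI -/-. An interaction of the knock-in with the wild-type allele, which is the difference of the differences given above, stays open. Its ribosomal value went from 0.42 to -0.43 with a term for MIWI +/KI replicates 1 and 2 and MIWI -/- replicate 2. The term rests on the MIWI -/- pair alone, so this change does not test the interaction. That term ended every call in MIWI -/KI against MIWI +/KI. All 485 genes called without it kept their direction, 414 of them within 1.5 times the former log2 fold change, 69 smaller and 2 larger, and the standard error was larger for 476 and smaller for 9 (median 0.17 before and 0.28 after). Itpr3os went from -4.30 (SE 0.19) to -3.94 (SE 0.29, adjusted p = 0.0767), Stambp from 2.98 (SE 0.18) to 3.08 (SE 0.32, adjusted p = 0.130) and Tnp1 from -1.56 (SE 0.26) to -2.44 (SE 0.25, adjusted p = 0.130). Larger standard errors thus went with most of the lost calls, though not with that of Tnp1, and the term also left 3 residual degrees of freedom in place of 4.

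The Piwil1 signal was higher in MIWI -/KI than in MIWI +/-, although each has 1 allele that is not null. Equal signal from each such allele would give no difference. The 0.85 (SE 0.17) is the pattern itself and so no separate test, and it lost its call under several alternatives. Signals that add up over alleles would put MIWI +/KI above MIWI -/KI by the signal of a wild-type allele. The mean intensities were 714 ± 48.9 and 684 ± 17.2 (SD, n = 2). A shift shared by the piRNA pathway would need its genes to rise as much, but the upper quartile of that list was 0.44. A higher transcript level from the knock-in allele, or a different match of its sequence to the probes, stays open and was not tested.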

How the results depend on the processing

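The added alternatives named in the methods were chosen after seeing the data; the others were planned, and leaving out probe sets with cross-match suffixes was not run because the cluster IDs are numbers. Unless the cause is named, the cause was not tested. The genes followed were Piwil1 and those taken by the rule for named genes, in the comparison that took them; of these, only Piwil1 in MIWI -/KI against MIWI +/KI reversed, 0.0087 without MIWI +/KI replicate 2. A 2-fold minimum took the counts to 688 (MIWI -/- against MIWI +/-), 708 (MIWI -/KI against MIWI +/-), 449 (without against with a wild-type allele) and 539 (genes shared by both mutants), by construction. The mean of a gene's clusters gave 2044, 1942, 1384 (MIWI -/KI against MIWI +/KI), 362 (MIWI +/KI against MIWI +/-), 5 (MIWI -/KI against MIWI -/-), 2540 (without against with), 590 (difference of the losses), and overlaps of 674 (separate controls) and 1411 (shared controls); it adjusts over fewer tests. Clusters listed with a gene gave 1100 for MIWI -/KI against MIWI +/KI, 193, 5, 279 for the difference of the losses and an overlap of 585. Clusters above the median level gave 909, 120, 3 and 173, with 5 lists called without against with a wild-type allele. No trend gave 2 for MIWI -/KI against MIWI -/-. Array weights gave 715 for MIWI -/KI against MIWI +/-, 252 against MIWI +/KI, 1799 for MIWI +/KI against MIWI +/- and an overlap of 229; only the groups compared gave 487, 100 and 1474. Quantile normalization and equal array medians each gave 0 for MIWI +/KI against MIWI +/-, and the latter moved an array's median by at most 0.0723. For Piwil1, 0.85 in MIWI -/KI against MIWI +/- lost its call with array weights and with only the groups compared; 0.91 in MIWI +/KI against MIWI +/- gained one with both (adjusted p = 0.00659 and 0.0167) and over clusters with a gene (0.0377), and 1.99 in MIWI -/KI against MIWI -/- above the median level (0.0152), without trend (0.0491) and over clusters with a gene (0.00287). With the replicate block the counts were 1166, 1144, 391, 0 for MIWI +/KI against MIWI +/-, 0, 1536 and 0. The labels do not say that equal numbers pair arrays. Deviations of same-numbered arrays correlated between -0.26 and 0.30, with the highest for MIWI +/- and MIWI -/-, which does not settle it. Crossed numbers for MIWI -/KI against MIWI -/- gave 0. The term for 3 arrays gave 584 for MIWI -/- against MIWI +/-, 0 for MIWI -/KI and MIWI +/- each against MIWI +/KI, an overlap of 0 and a shared one of 558, with 13, 7 and 6 lists called in MIWI -/- against MIWI +/-, MIWI -/KI against MIWI +/KI and without against with; the median standard error rose from 0.172 to 0.288. It reversed camera's direction, which is relative to the other genes, for lists, though the spermatocyte medians stayed above 0 (0.09 and 0.03), with adjusted p in MIWI -/KI against MIWI +/KI of 0.993 (spermatocyte), 0.0999 (Leydig), 0.137 (sex-linked), 1.47e-08 (ribosomal) and 0.000469 (respiratory); in MIWI +/KI against MIWI +/- of 0.186 (Sertoli), 1.02e-05 (ribosomal), 3.07e-06 (respiratory) and 0.0171 (proteasome); in MIWI -/KI against MIWI -/- of 0.971 (spermatocyte) and 0.225 (proteasome); and in the difference of the losses of 1.45e-12 (ribosomal), 9.04e-12 (respiratory) and 0.0223 (proteasome). Leaving out 1 array reversed camera's direction for the spermatocyte list in MIWI -/KI against MIWI +/- (0.773 without MIWI -/KI replicate 2, and 9.31e-06 to 0.773 over the arrays) and, in MIWI -/KI against MIWI -/-, the piRNA (0.775; 0.000218 to 0.972 over the arrays) and spermatocyte (0.0536) lists without MIWI -/KI replicate 2 and the spermatocyte (0.972; 6.08e-06 to 0.972) and proteasome (0.222; 2.06e-09 to 0.775) lists without MIWI -/- replicate 2. An estimated correlation left 1, 1, 0, 0, 0, 1 and 0 lists called in the 7 comparisons in the order of the methods, and fry 5 (MIWI -/KI against MIWI +/KI), 3 (MIWI +/KI against MIWI +/-), 0 (MIWI -/KI against MIWI -/-) and 3 (difference of the losses). Leaving out each array, in the order of the methods, gave counts of 375 to 2043, 344 to 2775, 42 to 2664, 0 to 27, 0 to 6, 654 to 3298 and 0 to 241, Piwil1 values of -1.33 to -0.96, 0.81 to 0.88, -0.13 to 0.01, 0.84 to 0.98, 1.81 to 2.18, -0.70 to -0.51 and 0.90 to 1.27, lists called of 6 to 13, 7 to 11, 7 to 12, 7 to 11, 3 to 10, 6 to 14 and 5 to 11, and overlaps of 42 to 764 and 290 to 1365; an array left alone in its genotype is assumed to vary like the others. Of the values of followed genes and lists, 1361 kept direction and call, 196 lost the call, 25 gained one and 14 reversed; leaving out arrays, the numbers were 1067, 131, 13 and 5. Low signal over background limits dim genes, and 2 arrays per genotype limit the rest.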

Other observations

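Gene families by symbol root, 631 in all, were searched after the results were seen, and the test of the dynein genes was chosen then; the test of the neighbours of Piwil1 was planned. Axonemal dynein heavy chains, the motors of the flagellum, rose in MIWI -/- against MIWI +/- in 9 of 15 measured genes, where 0.39 would be expected (adjusted p = 1.13e-07 over 5048 one-sided hypergeometric tests), and in 8 of 15 in MIWI -/KI (adjusted p = 7.56e-06). In MIWI -/- these were Dnah2 (1.31, SE 0.14), Dnah10 (1.13, SE 0.17), Dnah7b (0.99), Dnah7a (0.96), Dnah1 (0.94), Dnah7c (0.92), Dnah8 (0.65), Dnah3 (0.65) and Dnah17 (0.60). In the same comparison 9 of 29 Spata genes fell (adjusted p = 0.000358), among them Spata32 (-2.93), Spata18 (-2.07) and Spata3 (-1.90), and 11 of 37 Tex genes fell (adjusted p = 4.53e-05), among them Tex37 (-4.12) and Tex35 (-2.02), while Tex101 (2.38) and Tex14 (0.64) rose. Against the separate control, in MIWI -/KI against MIWI +/KI, 4 Spata and 4 Tex genes fell (adjusted p = 0.103 and 0.192), with medians of -0.24 and 0.14. Zinc finger genes of the Zfp root rose in MIWI -/KI, 29 of 347 against MIWI +/- (adjusted p = 0.000795) and 14 against MIWI +/KI (adjusted p = 0.0166), and 17 of 347 rose in MIWI -/- (adjusted p = 0.690). In all, the search called 7 families. Cfap was another, with 7 of 31 genes higher and 2 lower in MIWI -/- against MIWI +/- (hypergeometric adjusted p = 0.00500 for rises). In MIWI -/KI 5 Cfap genes rose against MIWI +/- (adjusted p = 0.294) and 1 against MIWI +/KI. Of 7 Heatr genes 4 rose in MIWI -/KI against MIWI +/- (adjusted p = 0.0118). Of 7 Tmco genes 4 fell in MIWI -/- (adjusted p = 0.0166) but 1 in MIWI -/KI, both against MIWI +/-. Family members of like sequence can share probes, so their counts are not independent.

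Genes that lost or gained expression without a wild-type allele differed in their level in MIWI +/KI. Of 172 genes that fell at least 2-fold in all 3 comparisons of a genotype without against one with a wild-type allele, 43 lay within 0.3 of MIWI +/- in MIWI +/KI on the log2 scale, 128 lay lower by more than that and 1 higher, with a median of -0.63. Itpr3os (0.08, SE 0.19) and Klk1b5 (-0.12, SE 0.23) had MIWI +/KI levels near those of MIWI +/-, while Acte1 (-1.19), Tex37 (-1.37) and Car2 (-1.22, limma adjusted p = 0.0455) were lower there. With the term for MIWI +/KI replicates 1 and 2 and MIWI -/- replicate 2, 18 of the 172 lay within 0.3 and 154 lower, with a median of -0.77, and none was called, against 5 without the term. There Itpr3os stood at -0.28 (SE 0.29), Klk1b5 at -0.42 (SE 0.39), Acte1 at -1.18 (SE 0.29), Tex37 at -0.92 (SE 0.29) and Car2 at -1.31 (SE 0.24, limma adjusted p = 1). The call of Car2 was also lost without any 1 array of MIWI +/-, MIWI +/KI or MIWI -/-, where no gene passed. Of 67 genes that rose at least 2-fold in all 3, 36 lay within 0.3 in MIWI +/KI and 29 lay higher (28 and 38 with that term), with Stambp at 0.02 (-0.07 with that term) and Morc1 at -0.13 but Prkx at 1.42 and Tdrd1 at 1.19. These genes were picked from comparisons that share arrays with MIWI +/KI, so the spread of values describes these arrays, and Itpr3os, Klk1b5, Stambp and Morc1 were chosen here after their values were seen, as were the other genes of this paragraph.

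Whether the rise of the dynein genes also holds against the other control stays open. In MIWI -/KI against MIWI +/KI, 14 of 15 Dnah genes had higher values, with a median of 0.20, although 1 of 15, Dnah7c (0.96), passed limma's threshold there, and the family test gave adjusted p = 1. Over all 19938 genes 45.1% had higher values there. The family was picked in part from MIWI -/KI against MIWI +/-, which shares the MIWI -/KI arrays, and its genes are not independent, so the count of 14 cannot decide it.

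Mice that carry a targeted allele often keep flanking sequence of the embryonic stem cell strain, which could change the levels of neighbouring genes. Of the 50 measured genes nearest to Piwil1, 25 on each side, 11 changed without against with a wild-type allele, where 4.13 would be expected (two-sided Fisher's exact p = 0.00216). Gm4868 (1.37, SE 0.13), Zbed5 (0.90, SE 0.14) and Gusb (0.82, SE 0.13) rose and Adgrd1 (-0.79, SE 0.15) and Septin14 (-0.78, SE 0.19) fell; Dnah10 (0.59) is also among the 11. Across the genome 134 of 18908 windows of that size (0.709%) held as many changed genes, with a median of 4 and a highest count of 14. For MIWI -/- against MIWI +/- alone the count was 5 (expected 3.06, Fisher's exact p = 0.232), for MIWI -/KI it was 8 against MIWI +/- (expected 3.11, exact p = 0.0115) and 2 against MIWI +/KI (expected 1.22, exact p = 0.344), and MIWI +/KI against MIWI +/- and MIWI -/KI against MIWI -/- had 0, with 0.0477 and 0 expected. Flanking sequence is therefore a candidate explanation for some of these neighbours, and strain markers that would decide it were not analysed here.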
